A study of Homo sapiens with 8 samples.

How the data were processed

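Messenger RNA of Hs 294T human melanoma cells was measured on 8 Affymetrix oligonucleotide arrays, 2 for each of 4 groups (DMSO, elesclomol, NAC, and elesclomol with NAC). Groups, doses and replicate numbers were taken from the labels, which describe the arrays of a group as technical replicates. The deposited values are linear intensity values, 1 per probe set and array, and MAS5 is named in the submitters' processing notes, with its version not given in the sources used here. Detection calls were not used here. The design written before the data were examined assumed signals scaled to a common target and planned no further normalization between arrays. The deposited values were not so scaled, since the mean without the lowest and highest 2% differed between arrays, so quantile normalization between arrays was used, a choice made after the brightness of the arrays was seen. The values as deposited, which the design would have used for the main fit, were fitted as an alternative.

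Of 54675 probe sets, 62 were controls and were left out of the tests. Of the other 54613, 41091 had 1 gene symbol in the platform annotation, 1801 had several and 11721 had none. Symbols were looked up by Entrez ID in a RefSeq gene table, where 41037 were found, 54 were not, and 0 symbols changed. No gene was named from a probe set with several symbols. After quantile normalization (limma 3.58.1 in R 4.3.3) a pseudocount of 0.825 (the 10th percentile of all signals) was added and log2 taken, so a fold change understates the change of dim genes. Probe sets had to exceed a signal of 9.325 (the 50th percentile) on at least 2 arrays, which 31837 did. Each gene was represented by its probe set with the highest mean, giving 13445 genes tested of 19775 with such probe sets.

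A linear model over all 8 arrays (limma lmFit and eBayes with a trend, 4 residual degrees of freedom) gave 6 contrasts: elesclomol, NAC and the combination each against DMSO, the combination against elesclomol and against NAC, and the interaction, which is the combination minus NAC, less elesclomol minus DMSO. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 1.5-fold. Adjusted p-values of genes are from limma, two-sided. Errors of log2 changes are standard errors from the model, and errors of signals are SDs over 2 arrays. With so few arrays no exact permutation test could pass the threshold, and their number limits the precision.

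Before the data were examined 23 gene lists were fixed, 4 of them markers of other cell types (fibroblasts, lymphocytes, keratinocytes and other epithelia, endothelium). Some lists shared members, mainly the glutathione, NRF2 and ATF4 lists, so results of these are not independent. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of a contrast. Genes to be named were fixed by rule: for each contrast, of the called genes for which both arrays of a group lay beyond both arrays of the other (for the interaction, of all called genes), the 8 largest rises and the 8 largest falls. To these were added up to 4 called members of each list with the largest absolute change, in the contrasts against DMSO and the interaction, and ACTB and GAPDH. The text names only part of these genes. That choice was made after the values were seen and leaned to genes outside the dim range whose call held when 1 array was left out. The totals of the closing section cover 134 values, which are only part of those the rule gives. They include fragile values but leave out others, such as BNIP3L (0.59) and BID (0.71) with elesclomol, both under 2-fold.

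Random lists of the same size matched on mean expression were drawn 10000 times. For contrasts that share arrays, unchanged groups were simulated against the shared DMSO arrays 20 times. The 3′ over 5′ ratios were computed from the control probe sets of ACTB and GAPDH, which entered no other comparison. Of 7 gene families tested after the values were seen, 1 is not reported here.

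The steps were tested on simulated data made for elesclomol versus DMSO with 13445 genes, of which 200 were changed. The changed genes were drawn only from those with a mean above a signal of 27.5 (the 70th percentile), so recovery of dimmer genes was not tested. Of the changed genes 24% were recovered at 1.5-fold, 76% at 2-fold, and 100% at 3-fold and at 4-fold. There were 10 false calls among 13245 unchanged genes, or 6.25% of the calls. Camera called 1 of 1 shifted list and 0 of 20 unshifted lists. The simulated genes varied independently of each other, so this does not test the effect of correlation between the genes of a list.

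Alternatives fixed before the data were examined were another pseudocount or none, another filter or none, equal array medians, all probe sets, the mean of a gene's probe sets, eBayes without a trend, only the arrays compared, no minimum change or a 2-fold minimum, the estimated correlation, the replicate number as a block, and each array left out in turn. Those added after the data were seen were a common trimmed mean (lowest and highest 2% left out) and a fit without the combination arrays. The values as deposited were the planned main scaling and became an alternative after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.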

Results

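Messenger RNA was measured in Hs 294T, an established human melanoma cell line, on 8 Affymetrix expression arrays of 54675 probe sets each. Elesclomol is a small molecule that binds copper and carries it into cells, and N-acetylcysteine (NAC) is a thiol antioxidant and cysteine donor. Cells received the vehicle DMSO (0.01%), elesclomol (100 nM), NAC (5 mM) or elesclomol with NAC, hereafter the combination, and were collected at 6 h. NAC was added 30 min ahead of the drug, and 3 h was given for attachment of the cells in all groups. The labels name DMSO for the DMSO arrays only, so whether the other groups also received it is not known here. Each of the 4 groups had 2 arrays, which the labels call technical replicates, so p-values measure only the spread between arrays and not the spread between cultures. Untreated cells, also named in the design text, were not analysed here.

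The arrays differed in brightness and in signs of RNA quality. The mean deposited signal without the lowest and highest 2% of probe sets was 43.3 and 35.9 on the DMSO arrays, 53.6 and 52.1 with elesclomol, 51.8 and 49.4 with NAC, and 34.9 and 29.8 with the combination. The ratio of the 3′ to the 5′ control probe set of ACTB, which rises as RNA is degraded or copied less completely, averaged 17.8 with DMSO, 13.9 with elesclomol, 11.1 with NAC and 45.2 with the combination (n = 2 arrays each). The same ratio of GAPDH averaged 3.63, 2.61, 2.14 and 5.65. After quantile normalization the arrays of a group correlated across 13445 genes at r = 0.961, 0.964, 0.966 and 0.947 in the same order, and arrays of different groups at 0.915 to 0.959 (genes are not independent replicates). The small number of arrays limits the precision of every value.

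**Figure D1:**
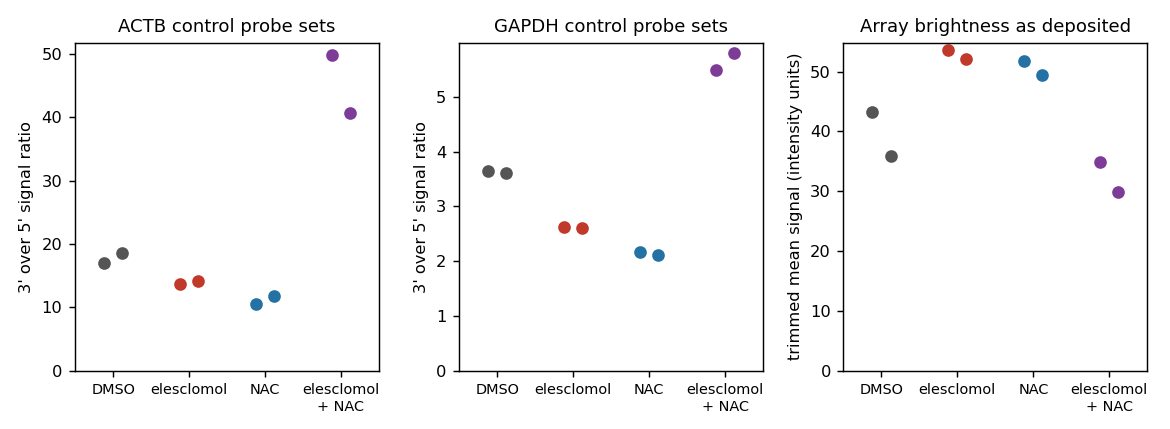
Brightness of each array (mean deposited signal without the lowest and highest 2% of probe sets) and the 3′ over 5′ signal ratios of ACTB and GAPDH on each array, by treatment group, each point being 1 array. The combination arrays had the highest ratios, 45.2 on average for ACTB and 5.65 for GAPDH, and the lowest brightness.

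Directions of small changes depended on how the arrays were scaled. The median log2 change of all genes after quantile normalization was −0.06 for elesclomol versus DMSO, 0.02 for NAC versus DMSO, 0.01 for the combination versus DMSO, 0.06 for the combination versus elesclomol, −0.01 for the combination versus NAC and 0.03 for the interaction. With the median of each array set equal these medians were 0.02, 0.22, −0.27, −0.28, −0.46 and −0.49, and with the values as deposited 0.33, 0.35, −0.22, −0.55, −0.55 and −0.90. With a common trimmed mean they were −0.09, −0.00, 0.06, 0.16, 0.10 and 0.17.

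The comparison of elesclomol with DMSO asked which transcripts changed after 6 h of the drug alone. Most genes of the heat shock, metallothionein and amino acid stress lists rose, as did 12 of 25 of the antioxidant list, and most of the cell cycle lists fell. HSPA6, a strictly inducible HSP70 chaperone, went from a normalized signal of 7.05 ± 1.41 (SD, n = 2 arrays) to 3156 ± 35.1, at least 338-fold higher (adjusted p = 4.06e-08). Where an array of a dim group lay under the filter signal of 9.325, a fold change is given as such a bound, with that array at the filter signal. HMOX1, which encodes heme oxygenase 1, rose 80.6-fold, from 34.3 ± 3.31 to 2826 ± 13.9. Of 13445 genes tested with limma, 761 were called higher and 1232 lower (adjusted p under 0.05 and a change of at least 1.5-fold), 70 of them at least 4-fold higher and 24 at least 4-fold lower.

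The other largest rises were those of DUSP2, a nuclear MAP kinase phosphatase (at least 18.9-fold, adjusted p = 0.000142), EID3 (log2 change 4.30 ± 0.43 SE), ZFAND2A, an arsenite-inducible regulator of the proteasome (3.93 ± 0.11), and SESN2, a stress-induced sestrin (3.51 ± 0.23). ARC also rose (at least 4.39-fold, adjusted p = 0.0322), but its fitted log2 change was 2.56 without DMSO replicate 2 and was then not called. Most of the largest falls were of dim genes, with all group signals under the 70th percentile of all signals, such as ADRB1 (at least 2.14-fold lower, adjusted p = 0.000421) and NRROS (at least 2.04-fold lower, adjusted p = 0.00146). TICRR, which acts in the start of DNA replication, fell at least 2.48-fold (adjusted p = 0.00183), but its other probe set went the opposite way and was not called, and the fitted log2 change was 0.08 without DMSO replicate 2 and 0.10 without NAC replicate 1, without combination replicate 1 or without combination replicate 2.

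Of 24 heat shock and cytosolic chaperone genes tested, 18 rose and 6 were not called, with a median log2 change of 1.14 (camera, adjusted p = 2.8e-25, and adjusted p = 0.00661 with an estimated correlation). Among them were DNAJB1, an HSP40 co-chaperone (2.87 ± 0.08), BAG3, a co-chaperone of HSP70 (2.64 ± 0.12), and DNAJB4 (2.40 ± 0.13). Of 8 metallothionein and zinc export genes, 7 rose (8 adjusted over the list alone), with a median of 2.16 (adjusted p = 8.32e-15, and adjusted p = 0.00661 with an estimated correlation). Metallothioneins bind zinc and copper, and MT1F rose 5.67-fold, MT1H by 2.49 ± 0.10 and MT1E by 2.49 ± 0.08. Whether the probe sets of these related genes each measured only their own gene was not tested, here or in the contrasts below. Of 25 genes of the NRF2 antioxidant list, 12 rose (13 adjusted over the list alone), with a median of 0.75 (adjusted p = 8.32e-15, and adjusted p = 0.00661 with an estimated correlation). They included GCLM, the modifier subunit of the enzyme that starts glutathione synthesis (2.71 ± 0.12), and SLC7A11, the cystine transporter (2.34 ± 0.15). Of 20 genes of the ATF4 integrated stress response, 14 rose, with a median of 1.11 (adjusted p = 2.12e-17, and adjusted p = 0.00661 with an estimated correlation). TRIB3, a pseudokinase induced by ATF4, rose by 2.99 ± 0.16 (its other probe set was not called), and CTH, which makes cysteine from cystathionine, by 2.61 ± 0.17.

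Smaller shifts were called for 4 further lists, each of which lost its call with an estimated correlation. Of 17 genes of the endoplasmic reticulum unfolded protein response 4 rose, with a median of 0.12 (adjusted p = 0.00714, and adjusted p = 0.084 with an estimated correlation). They included HERPUD1 (1.82 ± 0.09, its other probe set not called), DNAJB9 (1.57 ± 0.10) and the chaperone HSPA5 (0.72 ± 0.05). Of 27 proteasome genes 5 rose, with a median of 0.18 (adjusted p = 2.68e-06, and adjusted p = 0.173 with an estimated correlation), among them PSMD12 (1.04 ± 0.07, its other probe set not called), PSMD1 (0.85 ± 0.11) and PSMD2 (0.77 ± 0.08). Of 17 hypoxia genes 3 rose, with a median of 0.36 (adjusted p = 0.00261, and adjusted p = 0.0765 with an estimated correlation), the glucose transporter SLC2A3 by 1.23 ± 0.21. Of 21 glutathione and cysteine genes 5 rose (6 adjusted over the list alone), with a median of 0.15 (adjusted p = 0.00801, and adjusted p = 0.084 with an estimated correlation). GCLC, the catalytic partner of GCLM, rose by 1.26 ± 0.13, with 1 of its other 2 probe sets not called. Of these 21 genes 5 were also in another list, among them GCLM, GCLC, SLC7A11 and CTH, which all rose.

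Of 20 genes of the G2/M list 14 fell, with a median of −0.84 (adjusted p = 2.74e-09, and adjusted p = 0.0106 with an estimated correlation). AURKA, a mitotic kinase, changed by −1.33 ± 0.12, CDC20, an activator of the anaphase-promoting complex, by −1.10 ± 0.14, and TOP2A, a DNA topoisomerase, by −1.02 ± 0.11. Of 20 genes of DNA replication and S phase 14 fell (15 adjusted over the list alone), with a median of −0.72 (adjusted p = 6.39e-09, and adjusted p = 0.0106 with an estimated correlation). GINS1, part of the replicative helicase, changed by −1.25 ± 0.14, the cyclin CCNE1 by −1.04 ± 0.16, and MCM6 by −0.88 ± 0.09, where the other probe set of MCM6 had the opposite sign. The call of MCM6 was lost with the values as deposited (−0.34) and with the mean of its probe sets (−0.42).

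The other lists were not called. Of 21 immediate early genes 9 rose and 3 fell (median 0.20, adjusted p = 0.144), with DUSP1, a MAP kinase phosphatase, at 2.86 ± 0.26, the AP-1 subunit FOSB at 2.68 ± 0.33 and the orphan receptor NR4A1 at 2.34 ± 0.19. The other probe set of DUSP1 and both others of NR4A1 were not called. FOS (2.15 ± 0.71, adjusted p = 0.0493) lost its call without DMSO replicate 1 (2.09), DMSO replicate 2 (2.19), elesclomol replicate 1 (2.01) or elesclomol replicate 2 (2.27). Of 17 p53 targets 2 rose and 2 fell, or 3 adjusted over the list alone (median −0.21, mean 0.07, adjusted p = 0.971), GADD45A rising by 1.36 ± 0.08. Of 18 NF-kB and inflammatory genes 1 rose and 6 fell (median −0.11, adjusted p = 0.388), the chemokine CCL2 at −0.92 ± 0.05 and the cytokine LIF at −0.95 ± 0.08. With the values as deposited the calls of CCL2 (−0.33) and LIF (−0.39) were lost. Of 21 apoptosis regulators 3 rose (median −0.03, adjusted p = 0.476), PMAIP1, which encodes the BH3-only protein NOXA, by 1.64 ± 0.13. Of 13 cholesterol genes 1 rose, INSIG1, at 0.94 ± 0.08 (median 0.06, adjusted p = 0.208).

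Of 13 melanocyte lineage genes 2 fell (median −0.23, adjusted p = 0.454). SOX10, a neural crest transcription factor, changed by −1.67 ± 0.09, but its other probe set went the opposite way without a call, and the mean of its probe sets gave −0.44 with no call. PAX3 changed by −0.66 ± 0.22 and lost its call without DMSO replicate 1 (−0.68), DMSO replicate 2 (−0.65), elesclomol replicate 1 (−0.44), NAC replicate 1 (−0.66) or NAC replicate 2 (−0.66), and its other probe set was not called. Of 19 genes of copper handling and lipoylated enzymes 3 fell (median −0.05, adjusted p = 0.663), with SCO2, a copper chaperone of cytochrome c oxidase, at −1.26 ± 0.20. None of 34 respiratory chain genes (median −0.15, adjusted p = 0.29) and none of 29 ribosomal protein genes (median −0.03, adjusted p = 0.827) was called, 0 in each by limma, where 4594 of all genes had an unadjusted p under 0.05. The respiratory chain median was 0.13 with array medians equal, 0.45 with the values as deposited and 0.03 with a common trimmed mean, each 0.12 above the median of all genes, where after quantile normalization it lay 0.08 below. Markers of other cell types were not called as lists: fibroblast (2 of 10 fell, median −0.31, adjusted p = 0.579), lymphocyte (0 of 5, median 0.22, adjusted p = 0.579), keratinocyte and epithelial (1 of 5 fell, median −0.04, adjusted p = 0.985) and endothelial (0 of 2, median −0.48, adjusted p = 0.648). The epithelial marker that fell was KRT18 (−0.61 ± 0.08), whose change was 0.0031 with the values as deposited (median of all genes 0.33) and −0.58 without elesclomol replicate 2, neither of them called. In 4 of the 23 lists, none of them called, the median, the mean and the direction of the test were not all of 1 sign.

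The split of 761 higher to 1232 lower was 1037 to 879 with array medians equal and 2709 to 330 with the values as deposited. The control genes ACTB and GAPDH were not called, at −0.17 and −0.29, and were at 0.22 and 0.19 with the values as deposited, under the median of all genes (0.33). The medians of the 10 lists called kept their sign under each of the 3 other scalings.

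**Figure D2:**
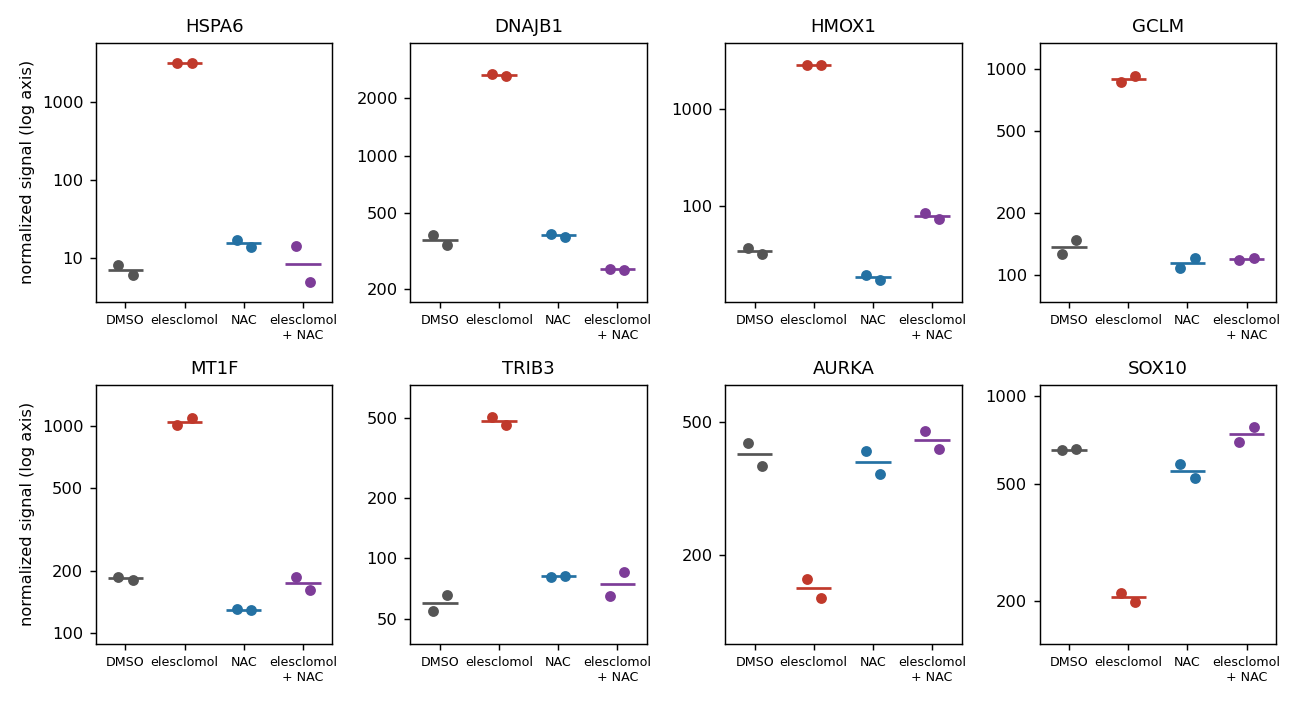
Normalized signal (log axis) of 8 genes in the 4 treatment groups, each point being 1 array and each line the geometric mean of 2 arrays. The signal of HSPA6 was 7.05 with DMSO, 3156 with elesclomol, 15.3 with NAC and 9.51 with the combination.

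The comparison of NAC with DMSO asked what the antioxidant did alone. RARS1, which encodes arginyl-tRNA synthetase, rose 3.10-fold, from a normalized signal of 328 ± 44.1 (SD, n = 2 arrays) to 1021 ± 144. MT1X, a metallothionein, and TXNRD1, the cytosolic thioredoxin reductase, changed by −0.95 ± 0.07 and −0.68 ± 0.07 on the log2 scale. The comparison called 187 genes higher and 144 lower, 4 and 3 of them by at least 4-fold. GLB1L2 (at least 3.73-fold lower, adjusted p = 0.004) and ATP8B1 (−1.34 ± 0.18) were among the largest falls, and MCTS1 (1.33 ± 0.16, its other probe set of opposite sign) among the largest rises. HMOX1 changed by −0.86 ± 0.14, and by −0.76 without DMSO replicate 1, where it was not called. The NRF2 list was not called: of 25 genes 0 rose (2 adjusted over the list alone) and 3 fell, with a median of 0.06 and a test in the lower direction (adjusted p = 0.68).

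Of 6 lists called with NAC, none held with an estimated correlation, and the NAC arrays had the lowest 3′ over 5′ ratios (ACTB 11.1, DMSO 17.8). Of 27 proteasome genes 3 rose (median 0.22, adjusted p = 0.000154, and adjusted p = 0.295 with an estimated correlation). Of 29 ribosomal protein genes 2 rose (median 0.16, adjusted p = 0.00363, and adjusted p = 0.228 with an estimated correlation), RPS14 by 0.61 ± 0.05. Of 34 respiratory chain genes 2 rose (median 0.10, adjusted p = 0.0159, and adjusted p = 0.228 with an estimated correlation), among them ATP5F1A, the alpha subunit of ATP synthase (0.70 ± 0.09). Of 24 heat shock genes 1 rose, or 2 adjusted over the list alone (median 0.14, adjusted p = 0.00363, and adjusted p = 0.228 with an estimated correlation). It was HSPA4L (0.66 ± 0.15), whose call was lost without DMSO replicate 1 (0.70), DMSO replicate 2 (0.62), NAC replicate 1 (0.54) or NAC replicate 2 (0.77). Of 8 metallothionein and zinc export genes 1 fell, MT1X, whose other probe set was not called (median −0.43, 0.00 with the values as deposited and then 0.35 below the median of all genes, adjusted p = 2.78e-05, and adjusted p = 0.169 with an estimated correlation). Of 21 immediate early genes 1 rose and 2 fell, or 3 fell adjusted over the list alone (median −0.06, 0.15 with array medians equal and 0.29 with the values as deposited, both 0.07 below the median of all genes, adjusted p = 0.0331, and adjusted p = 0.228 with an estimated correlation).

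Without the trend in the variance model limma called 0 genes for NAC, where 2232 had an unadjusted p under 0.05 and the trended model had 2671. Leaving out DMSO replicate 1, DMSO replicate 2, NAC replicate 1 or NAC replicate 2 gave 94, 67, 75 or 59 genes higher, and leaving out DMSO replicate 1, DMSO replicate 2 or NAC replicate 2 gave 76, 75 or 92 lower. The split was 847 to 45 with array medians equal and 2060 to 41 with the values as deposited. The calls of MT1X and TXNRD1 were lost under both of these scalings (MT1X −0.56 and −0.43, TXNRD1 −0.31 and −0.17), and that of TXNRD1 also with a common trimmed mean (−0.53).

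The comparison of the combination with DMSO asked what remained of the changes when both compounds were present. HMOX1 rose 2.27-fold, to a normalized signal of 79.0 ± 8.64 (SD, n = 2 arrays), and SOD2, the mitochondrial superoxide dismutase, rose 2.63-fold. Of 34 respiratory chain genes tested, 12 fell and 22 were not called, with a median log2 change of −0.39 (adjusted p = 7.11e-10, and adjusted p = 0.039 with an estimated correlation). The comparison called 660 genes higher and 844 lower, 22 and 37 of them by at least 4-fold. The combination arrays had the highest 3′ over 5′ ratios (ACTB 45.2, DMSO 17.8). The control genes ACTB (−0.37 ± 0.04, limma adjusted p = 0.000184) and GAPDH (−0.57 ± 0.05, limma adjusted p = 3.02e-05) were lower by less than 1.5-fold and so were not called. GAPDH was called lower with array medians equal (−0.77) and with the values as deposited (−0.72), where the medians of all genes were −0.27 and −0.22.

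The respiratory chain genes with the largest falls were CYC1, cytochrome c1 (−1.26 ± 0.13), NDUFV2 (−1.23 ± 0.15) and NDUFB10 (−1.21 ± 0.12, its other probe set not called), both complex I subunits, and COX8A of complex IV (−1.11 ± 0.09). Of 27 proteasome genes 6 fell (median −0.36, adjusted p = 1.39e-05, and adjusted p = 0.363 with an estimated correlation), PSMB5, which carries the chymotrypsin-like activity, at −1.49 ± 0.12. Of 29 ribosomal protein genes 2 fell (median −0.23, adjusted p = 0.00113, and adjusted p = 0.345 with an estimated correlation), RPL3 at −1.03 ± 0.08. Of 17 unfolded protein response genes 1 rose and 3 fell (median −0.26, adjusted p = 0.00106, and adjusted p = 0.17 with an estimated correlation), the disulfide isomerase PDIA4 at −1.43 ± 0.09 with its other probe set not called. The heat shock list had 1 rise and 6 falls among 24 and was not called (adjusted p = 0.255), with the co-chaperone STIP1 at −1.11 ± 0.11 and its other probe set not called. No metallothionein list member was called, 0 of 8 by limma, where 4306 of all genes had an unadjusted p under 0.05 (list median 0.12, adjusted p = 0.789). Among the named genes outside the dim ones the largest fitted fall was that of KBTBD4, at least 2.45-fold (adjusted p = 0.000158). The glutathione peroxidases GPX1 and GPX4 changed by −1.18 ± 0.09 and −0.89 ± 0.14. Among the largest rises, CASKIN1 (adjusted p = 0.0153) lost its call without DMSO replicate 2 or combination replicate 2 (fitted log2 changes 2.24 and 2.64).

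Across genes, the changes with elesclomol and with the combination, both against DMSO, correlated at r = 0.290. Simulated unchanged groups that shared the DMSO arrays gave 0.497, and the covariance was 0.114 against a simulated 0.0851. No gene changed in the simulated groups, so their r comes from the shared arrays alone. It sets no level for the r of groups in which genes do change. Of the genes called, 115 were higher in both (37.4 with independent lists), 117 lower in both (77.3) and 99 went opposite ways. Part of the excess may come from the shared DMSO arrays. For elesclomol and NAC the values were r = 0.375 (simulated 0.50), a covariance of 0.119 (simulated 0.0856), 43 genes higher in both (10.6), 46 lower in both (13.2) and 15 opposite. For NAC and the combination they were r = 0.300 (simulated 0.499), a covariance of 0.0893 (simulated 0.0856), 12 higher in both (9.18), 26 lower in both (9.04) and 32 opposite. The split of 660 to 844 was 131 to 2402 with array medians equal and 153 to 2033 with the values as deposited, and 541 genes were lower without DMSO replicate 1.

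The comparison of the combination with elesclomol asked what the addition of NAC changed in cells given the drug. HSPA6 fell at least 275-fold (adjusted p = 3.8e-08), from a normalized signal of 3156 ± 35.1 (SD, n = 2 arrays) to 9.51 ± 6.50, and HMOX1 fell 35.5-fold. ZFAND2A fell 15.3-fold and SESN2 10.8-fold. Of 24 heat shock genes 19 fell (median −1.51, adjusted p = 1.09e-17, and adjusted p = 0.00788 with an estimated correlation), and of 25 NRF2 list genes 21 fell (median −0.93, adjusted p = 2.1e-14, still called with an estimated correlation). The comparison called 1827 genes higher and 1450 lower.

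The metallothionein list had 7 falls among 8 (median −1.95, adjusted p = 8.23e-11) and the ATF4 list 16 among 20 (median −1.33, adjusted p = 3.78e-14), and both held with an estimated correlation. The unfolded protein response list had 7 falls among 17 (median −0.46), the glutathione list 10 falls and 1 rise among 21 (median −0.42) and the respiratory chain list 9 falls among 34 (median −0.31), each still called with an estimated correlation (adjusted p = 0.0241, 0.0326 and 0.0246). The calls of 3 lists were lost with it: proteasome, 17 of 27 lower (median −0.70, adjusted p = 3.26e-11, and adjusted p = 0.0664 with an estimated correlation), hypoxia, 7 of 17 (median −0.32, adjusted p = 0.0218, and adjusted p = 0.11 with an estimated correlation) and ribosomal proteins, 3 of 29 (median −0.12, adjusted p = 0.00191, and adjusted p = 0.119 with an estimated correlation). The G2/M list had 11 rises among 20 (median 0.63) and the S phase list 9 among 20 (median 0.54), both held with an estimated correlation (adjusted p = 0.0326). With the values as deposited their medians turned to −0.07 and −0.20, which lay 0.48 and 0.35 above the median of all genes. The split of 1827 to 1450 was 627 to 3395 with array medians equal and 280 to 5129 with the values as deposited, and the ACTB 3′ over 5′ ratio was 45.2 against 13.9 with elesclomol.

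The comparison of the combination with NAC asked what elesclomol did in cells given NAC. HMOX1 rose by 2.04 ± 0.14 on the log2 scale, from a normalized signal of 18.5 with NAC to 79.0 with the combination (it was chosen after its values were seen). KBTBD4 was at least 3.27-fold lower (adjusted p = 3.6e-05) and LSM2, part of the U6 small nuclear ribonucleoprotein, at least 4.40-fold lower (adjusted p = 0.00326), the latter not called without the trend in the variance model. Of 34 respiratory chain genes 14 fell, with a median of −0.53 (adjusted p = 2.76e-12, and adjusted p = 0.0256 with an estimated correlation). The comparison called 991 genes higher and 1430 lower, 18 and 52 of them by at least 4-fold.

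The 6 other lists called here lost the call with an estimated correlation, and the ACTB 3′ over 5′ ratio was 45.2 with the combination and 11.1 with NAC. Of 24 heat shock genes 1 rose and 9 fell, or 10 fell adjusted over the list alone (median −0.51, adjusted p = 0.00592, and adjusted p = 0.16 with an estimated correlation). Of 8 metallothionein and zinc export genes 2 rose (adjusted p = 0.000721, and adjusted p = 0.146 with an estimated correlation), with a median of 0.41 that turned to −0.29 with array medians equal and −0.38 with the values as deposited, each 0.17 above the median of all genes. Of 27 proteasome genes 13 fell (median −0.58, adjusted p = 1.28e-08, and adjusted p = 0.16 with an estimated correlation). Of 29 ribosomal protein genes 6 fell (median −0.27, adjusted p = 1.06e-05, and adjusted p = 0.146 with an estimated correlation). Of 17 unfolded protein response genes 1 rose and 5 fell (median −0.30, adjusted p = 0.00566, and adjusted p = 0.146 with an estimated correlation). Of 19 genes of copper handling 1 rose and 4 fell (median −0.33, adjusted p = 0.0379, and adjusted p = 0.282 with an estimated correlation). The split of 991 to 1430 was 128 to 4561 with array medians equal and 100 to 5260 with the values as deposited. BST2 (at least 2.59-fold lower, adjusted p = 0.0287) lost its call without NAC replicate 1, NAC replicate 2 or combination replicate 2 (fitted log2 changes −2.67, −2.65 and −0.94).

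The interaction asked whether elesclomol changed a gene differently with NAC (combination minus NAC) than without it (elesclomol minus DMSO). The response of HSPA6 was at least 449-fold lower with NAC (adjusted p = 5.28e-07), and that of HMOX1 19.6-fold lower (log2 difference −4.29 ± 0.20), and that of DNAJB1 differed by −3.47 ± 0.12 (n = 2 arrays per group). The response of AURKA was 2.95-fold higher and that of PCNA, the sliding clamp of DNA polymerase, 2.31-fold higher. The interaction was called for 1751 genes higher and 1526 lower.

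Of 24 heat shock genes 19 had a lower response with NAC (median −1.91, adjusted p = 8.71e-18, and adjusted p = 0.014 with an estimated correlation), BAG3 at −2.58 ± 0.16. The metallothionein list had 7 lower among 8 (median −1.45, adjusted p = 1.34e-08), MT1H at −2.20 ± 0.14 and MT1F at −2.09 ± 0.15. The NRF2 list had 18 lower among 25, or 20 adjusted over the list alone (median −1.15, adjusted p = 2.53e-12), GCLM at −2.64 ± 0.17. The ATF4 list had 13 lower among 20 (median −1.26, adjusted p = 3.59e-10), SESN2 at −3.65 ± 0.33, TRIB3 at −3.12 ± 0.22 (its other probe set not called) and DDIT3, which encodes CHOP, at −2.60 ± 0.33. The unfolded protein response list had 8 lower and 1 higher among 17 (median −0.57, adjusted p = 0.000168), HERPUD1 at −2.05 ± 0.12 with its other probe set not called. The glutathione list had 10 lower among 21, or 12 adjusted over the list alone (median −0.65, adjusted p = 0.000289), CTH at −2.02 ± 0.24. Among the lower genes of the glutathione list, CTH, GCLM, GCLC and SLC7A11 were also in the NRF2 or ATF4 lists. These lists held with an estimated correlation, with adjusted p = 0.0205, 0.014, 0.0156, 0.0428 and 0.0428 in the order from metallothioneins to glutathione, and so did the respiratory chain list, 13 lower among 34 (median −0.40, adjusted p = 0.0211), COX8A at −1.46 ± 0.13, beside ACTB 3′ over 5′ ratios of 45.2 with the combination, 11.1 with NAC, 13.9 with elesclomol and 17.8 with DMSO.

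The proteasome list had 18 lower among 27 (median −0.93, adjusted p = 5.49e-12, and adjusted p = 0.0648 with an estimated correlation), PSMC3 at −1.79 ± 0.20. The hypoxia list had 7 lower among 17 (median −0.50, adjusted p = 0.00532, and adjusted p = 0.0655 with an estimated correlation) and the ribosomal list 11 among 29 (median −0.30, adjusted p = 0.000327, and adjusted p = 0.0794 with an estimated correlation), with the same ACTB 3′ over 5′ ratios (45.2 with the combination, 11.1 with NAC, 13.9 with elesclomol, 17.8 with DMSO). The G2/M list had 8 higher, or 10 adjusted over the list alone, and 1 lower among 20 (adjusted p = 0.0055, and adjusted p = 0.0655 with an estimated correlation), with a median of 0.52 that turned to −0.07 with array medians equal and −0.45 with the values as deposited, 0.43 and 0.44 above the median of all genes. The S phase list had 8 higher among 20, or 12 adjusted over the list alone (adjusted p = 0.000763, and adjusted p = 0.0498 with an estimated correlation), with a median of 0.72 that turned to −0.15 and −0.55, 0.35 and 0.34 above the median of all genes. PCNA (1.21 ± 0.10) was at −0.24 with the values as deposited (median of all genes −0.90), and the calls of PCNA and AURKA were lost under both of these scalings. SOX10 was at 2.09 ± 0.13, but at 0.06 without a call for the mean of its probe sets, of which the other had the opposite sign. The split of 1751 to 1526 was 323 to 3893 with array medians equal and 116 to 6105 with the values as deposited. The control genes ACTB (−0.09) and GAPDH (−0.03) were not called. GAPDH was called lower with array medians equal (−0.78) and with the values as deposited (−1.18), and ACTB with the latter (−0.64). The medians of all genes were then −0.49 and −0.90.

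**Figure D3:**
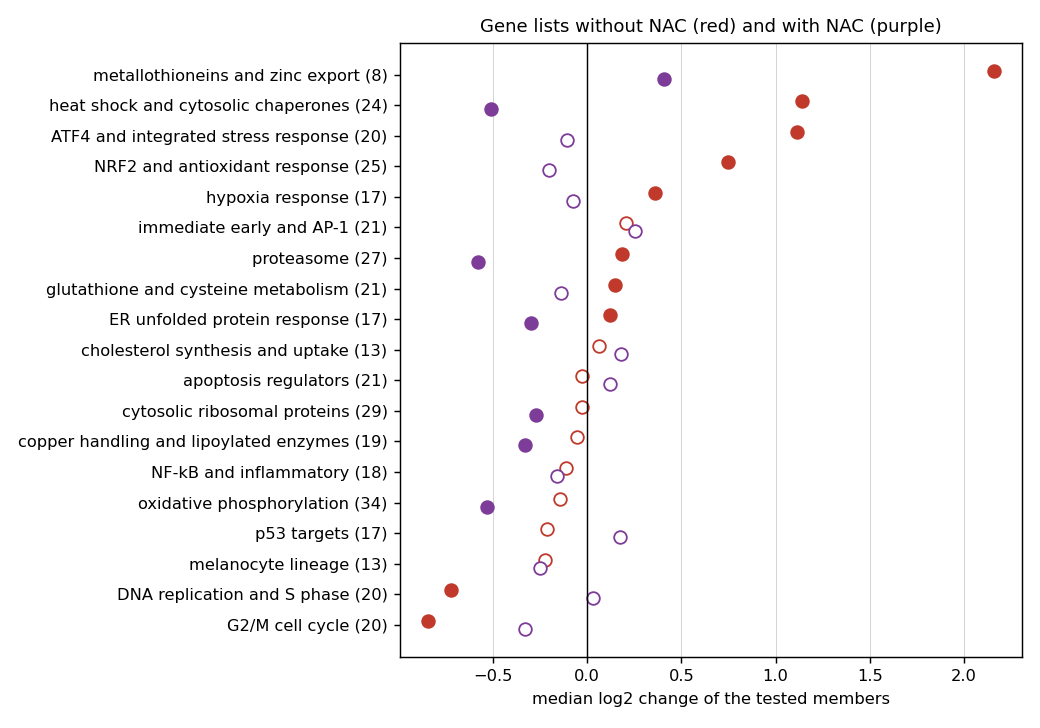
Median log2 change of 19 gene lists, in red for elesclomol versus DMSO and in purple for the combination versus NAC, filled where camera called the list with its preset correlation and open where it did not. The heat shock median was 1.14 without NAC and −0.51 with it, and the metallothionein median 2.16 and 0.41, the latter −0.29 with array medians equal and −0.38 with the values as deposited, each 0.17 above the median of all genes.

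The genes called with elesclomol alone were followed in the comparison of the combination with NAC, which shares no array with elesclomol versus DMSO. The 761 genes called higher had a median change of 0.94 with elesclomol alone and of 0.03 with NAC present (quartiles −0.37 and 0.43). Random lists of the same size matched on expression gave −0.06 to 0.04 (central 95% of 10000 lists). Of these genes 94 were called higher (56.1 with independent lists) and 98 lower (80.9) with NAC present, and 476 were called lower in the interaction against 2 higher. The 1232 genes called lower had a median of −0.83 alone and of 0.11 with NAC present, above the random lists (−0.05 to 0.03), with 110 called lower (131 with independent lists), 162 higher (90.8) and 805 higher in the interaction against 3 lower. The interaction subtracts the change by which these genes were chosen, so the directions of its counts were largely set by that choice. Over the 1993 genes the slope of the change with NAC on the change without it was −0.00864 (−0.0283 to 0.0126 on leaving out 1 array). The median of 0.03 was 0.0702 without DMSO replicate 2, 0.0677 without elesclomol replicate 1, −0.0255 without elesclomol replicate 2 and −0.0228 without combination replicate 2. With array medians equal and with the values as deposited, the median of the 761 genes with NAC present turned to −0.58 and −0.70, or −0.115 and −0.153 relative to the median of all genes. The median of the 1232 genes turned to −0.45 and −0.54, which lay 0.02 and 0.008 above the median of all genes.

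**Figure D4:**
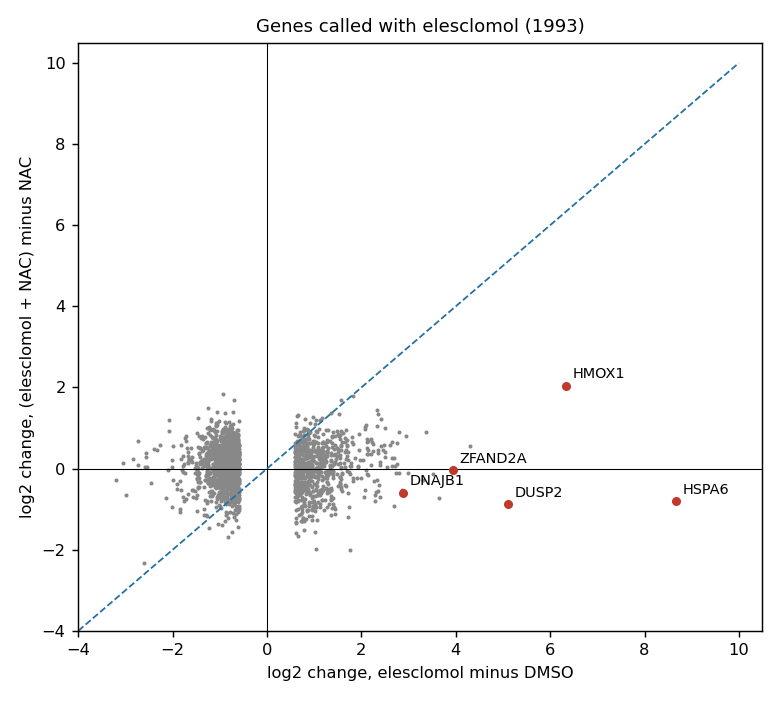
Log2 change of the 1993 genes called with elesclomol, without NAC on the horizontal axis (elesclomol minus DMSO) and with NAC on the vertical axis (combination minus NAC), each point being 1 gene and the dashed line marking equal change. The slope was −0.00864, and of the named genes HMOX1 lay at 6.33 without NAC and 2.04 with it.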

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

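All tests of explanations in this part were chosen after the results were seen. The response to elesclomol differed with and without NAC, by the interaction test, for 1751 genes higher with NAC and 1526 lower. The 3′ over 5′ ratios, from control probe sets outside the comparisons, stood out in the combination arrays: 45.2 for ACTB (17.8 with DMSO) and 5.65 for GAPDH (3.63 with DMSO).

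The response to elesclomol was largely absent when NAC was present: the slope of the change with NAC on the change without it was −0.00864 over 1993 genes. RNA quality of the combination arrays was examined in genes with at least 2 probe sets called alike with elesclomol. Relative to all probe sets, the best kept one had a median of 0.308 of its gene's change for 284 raised genes and 0.188 for 232 lowered genes. The 95% intervals over genes reached at most 0.461 in 3 scalings, under a cut-off of 0.5 set after the results were seen. The best probe set kept at least 0.5 in 81 of the raised and 64 of the lowered genes, and in 114 of 278 lowered genes with a common trimmed mean. Probe set positions were not used, so genes with no spared probe set were not set apart. The share kept by the best probe set therefore cannot by itself decide whether RNA quality was the whole cause. All 1232 lowered genes had a median of −0.83 with elesclomol alone and of 0.11 in the combination against NAC (quartiles −0.26 and 0.41). Relative to all genes the latter was 0.02 with array medians equal and 0.008 with the values as deposited. Poorer RNA alone would not restore lowered genes, so these values argue against it as the whole cause for the lowered genes. RNA quality as a part of the cause stays open. Combination cells that received no elesclomol could not be told apart from cells in which NAC acted. In the combination against NAC HMOX1 rose by 2.04 ± 0.14, SLC7A11 by 1.34 ± 0.15 and MT1E by 0.99 ± 0.08. MT1G (0.62 ± 0.12) and CTH (0.59 ± 0.17) were called higher too. Of other genes raised by elesclomol, DNAJB1 fell (−0.59 ± 0.08), and HSPA6, ZFAND2A, SESN2, TRIB3 and GCLM were not called. These genes were chosen after their values were seen. Of the 761 genes higher with elesclomol, 94 were called higher (56.1 expected from the share of all genes). But so were 162 of the 1232 genes lower with it (90.8 expected), and only 7 of the 70 genes at least 4-fold higher (5.16 expected). An action of NAC on the response, or on the drug itself, may account for the loss and was not tested. The arrays are technical replicates, so a difference between cultures also stays open.

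The changes of the combination against DMSO were measured on the arrays with the highest 3′ over 5′ ratios. Probe sets of 1 gene, which lie at different distances from the 3′ end, differed in their log2 change by an SD of 0.432 after array noise, 1.71 times that of NAC against DMSO (95% interval 1.63 to 1.80 over 1000 resamples of 2324 genes, not of arrays), where elesclomol gave 1.07 times. Part of these changes may therefore come from RNA quality, as its values were as that explanation requires. A real change of transcript ends was not tested and stays open. The test gives no share of the 1504 calls against DMSO, or of the calls of the other contrasts, that RNA quality accounts for.

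The respiratory chain, proteasome and ribosomal lists were higher with NAC alone, with the lowest 3′ over 5′ ratios, and lower with the combination, with the highest, but with an estimated correlation only the respiratory chain list held with the combination against DMSO (adjusted p = 0.039; proteasome 0.363, ribosomal 0.345) and none held with NAC alone (adjusted p = 0.228, 0.295 and 0.228). Across 5235 genes in the upper part of the signal range that were not called with elesclomol, the change with NAC alone and the change of the combination against elesclomol correlated at r = −0.185, but across all 13445 genes at −0.0814, so RNA quality differing between groups could not be told apart. Array brightness could not be told apart: with elesclomol, whose arrays were brighter by a similar factor, the respiratory chain median less that of all genes was −0.0842 with 0 members called higher by limma (4594 of all genes at an unadjusted p under 0.05), but 0.12 with array medians equal and 0.12 with a common trimmed mean. RNA quality and a biological effect of NAC on these genes both stay open.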

How the results depend on the processing

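Quantile normalization, the common trimmed mean and the fit without the combination arrays were chosen after the data were seen. The values as deposited were the scaling planned beforehand. Counts are given as genes higher and lower. The cause of each shift was not tested unless named. With so few arrays and no detection calls used, signal over background limits the dim genes most. Of 134 named gene values, a part of those the naming rule gives, 78 kept their call and direction in each setting run and 3 reversed in some setting. Per setting, the call was lost for 12 with array medians equal, 20 with the values as deposited, 3 with a common trimmed mean, 12 with the mean of a gene's probe sets, 24 without the trend and 28 with a 2-fold minimum, and for 1 to 3 with another pseudocount or none, no filter or all probe sets. In fits that left out an array the call was lost for 2 to 14. The deviations of arrays with the same replicate number correlated at 0.0301 to 0.066 between groups, under a threshold of 0.1, so the arrays were not paired by number. With a replicate block elesclomol against DMSO gave 809 and 1294 (761 and 1232 without it) and NAC 243 and 181 (187 and 144). None of the 134 named gene calls was lost with the block. A weak effect shared by arrays of the same number stays open. Without the combination arrays elesclomol gave 834 and 1342 and NAC 236 and 162.

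With all probe sets, where more features are tested, the counts were 1925 and 2104 for elesclomol, 361 and 457 for NAC, 1470 and 2063 for the combination against DMSO, 3498 and 3729 against elesclomol, 2596 and 3333 against NAC, and 3291 and 3379 for the interaction, and the medians in the combination against NAC of what elesclomol raised and lowered were 0.0756 and 0.15. With a 2-fold minimum, which by construction calls fewer, they were 341 and 352, 24 and 24, 144 and 270, 741 and 665, 233 and 529, and 950 and 898 in the same order, and the first of those medians was 0.11. With no minimum change they were 1171 and 1957 for elesclomol, 402 and 351 for NAC, 1212 and 1370 for the combination against DMSO and 1728 higher against NAC. With the mean of a gene's probe sets they were 121 and 52 for NAC, and 281, 1173, 468 and 985 higher for the combination against DMSO, elesclomol and NAC and for the interaction, with 7 lists called for the combination against DMSO and medians of −0.0524 and 0.00119. Without the trend NAC had 0 and 0 (limma, 2232 genes at an unadjusted p under 0.05) and 2 lists, and the combination against DMSO 400 higher. With an estimated correlation 6 lists were called for elesclomol, 0 for NAC, 1 for the combination against DMSO and 1 against NAC.

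With array medians equal the counts were 847 and 45 for NAC, 131 and 2402 for the combination against DMSO (9 lists), 627 and 3395 against elesclomol, 128 and 4561 against NAC and 323 and 3893 for the interaction, and the medians of the genes elesclomol raised and lowered were −0.58 and −0.45, the latter reversed. With the values as deposited they were 2709 and 330, 2060 and 41, 153 and 2033, 280 and 5129, 100 and 5260, and 116 and 6105 in the order of contrasts above, with medians of −0.70 and −0.54, the latter reversed. These scalings move the median of all genes, and the reversed medians lay 0.02 and 0.008 above it, those of the genes raised at −0.115 and −0.153 relative to it. With the values as deposited KRT18 in elesclomol against DMSO (0.0031) and PCNA in the interaction (−0.24) reversed, where the medians of all genes were 0.33 and −0.90. Leaving out 1 array, with a lone array assumed to vary like the other groups, gave 59 to 222 higher and 75 to 160 lower for NAC (94 and 76 without DMSO replicate 1, 67 and 75 without DMSO replicate 2, 75 and 108 without NAC replicate 1, 59 and 92 without NAC replicate 2) and 541 to 1042 lower for the combination against DMSO (541 without DMSO replicate 1). The medians in the combination against NAC of the genes elesclomol raised and lowered ranged from −0.0255 (without elesclomol replicate 2; −0.0228 without combination replicate 2) to 0.0702 (without DMSO replicate 2; 0.0677 without elesclomol replicate 1) and from 0.0888 to 0.15. TICRR in elesclomol against DMSO ranged from −3.78 to 0.10 and was 0.10 without the combination arrays, reversed because its other probe set then had the higher mean and was taken (0.08 without DMSO replicate 2, 0.10 without NAC replicate 1 or either combination replicate).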

Other observations

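Gene families outside the fixed lists were chosen after their values were seen, as were their tests, and 7 families were tested. With elesclomol, cytosolic aminoacyl-tRNA synthetases, which charge tRNAs and include ATF4 targets, had 6 rises among 17 (median 0.43, adjusted p = 4.67e-05, and adjusted p = 0.0607 with an estimated correlation), with SARS1 at 1.42 ± 0.12, GARS1 at 1.25 ± 0.07 and YARS1 at 1.07 ± 0.10. Their response was lower with NAC (10 of 17 in the interaction, median −0.75, adjusted p = 0.00167, and adjusted p = 0.0747 with an estimated correlation), YARS1 at −1.90 ± 0.14, beside ACTB 3′ over 5′ ratios of 45.2 with the combination, 11.1 with NAC, 13.9 with elesclomol and 17.8 with DMSO. HOX genes, transcription factors of body patterning, had 9 falls among 25 (median −0.68, adjusted p = 0.000658, and adjusted p = 0.0607 with an estimated correlation), with HOXC9 at −1.24 ± 0.15 and HOXB7 at −1.05 ± 0.10. The medians of both families with elesclomol kept their sign under each scaling. In the interaction, with the same ACTB ratios (45.2 with the combination, 11.1 with NAC), 10 HOX genes were higher, with a median of 0.78 that turned to −0.01 with the values as deposited (1 rise), 0.89 above the median of all genes (adjusted p = 0.00167, and adjusted p = 0.0747 with an estimated correlation). Tubulins were picked by symbols that start with TUBA, TUBB or TUBG, which also match genes of gamma-tubulin complex proteins (TUBGCP). The genes so picked had 6 falls among 21 with elesclomol (adjusted p = 4.67e-05, and adjusted p = 0.0607 with an estimated correlation), TUBB4B at −1.01 ± 0.06. Their median of −0.42 turned to 0.07 with the values as deposited (0 falls, camera adjusted p = 0.0306), 0.26 below the median of all genes.

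Genes of mitochondrial ribosomal proteins had 5 rises among 75 with NAC (median 0.22, adjusted p = 2.44e-05, and adjusted p = 0.266 with an estimated correlation) and 21 falls and 3 rises with the combination against DMSO (median −0.34, adjusted p = 2.23e-07, and adjusted p = 0.259 with an estimated correlation). Against NAC 37 fell with the combination (median −0.54, adjusted p = 1.12e-10, and adjusted p = 0.15 with an estimated correlation). The medians of these 3 contrasts kept their sign under each scaling, and the ACTB 3′ over 5′ ratios were 17.8 with DMSO, 11.1 with NAC and 45.2 with the combination. With elesclomol 10 fell (adjusted p = 0.00295, and adjusted p = 0.253 with an estimated correlation), with a median of −0.20 that was 0.27 with the values as deposited (11 rises and 0 falls, camera adjusted p = 0.999), 0.06 below the median of all genes. With array medians equal there were 1 rise and 4 falls, and the call was lost (adjusted p = 0.225). Zinc finger genes named ZNF, mostly of unknown targets, had 40 rises and 7 falls among 388 with the combination against DMSO (adjusted p = 0.00229, and adjusted p = 0.0122 with an estimated correlation), with a median of 0.21 that turned to −0.06 with array medians equal (5 rises and 23 falls, adjusted p = 0.595 with an estimated correlation) and −0.02 with the values as deposited (5 rises and 18 falls, adjusted p = 0.567 with an estimated correlation), each 0.21 above the median of all genes. With elesclomol the ZNF genes (35 rises, 39 falls, median −0.01, adjusted p = 0.246) and the kinesins (3 rises and 10 falls among 31, median −0.36, or 0.15 with the values as deposited and then 0.19 below the median of all genes, adjusted p = 0.154) were not called as families.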
